A study of Arabidopsis thaliana with 13 samples.

How the data were processed

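Seedlings of Arabidopsis thaliana were grown in liquid medium, and per the labels' protocols total RNA was extracted with TRIzol, 5 µg of it was reverse transcribed, and biotin-labelled cRNA was hybridised at a service centre, which returned normalized values and expression calls. A growth time of 6 days is given for the Col-0 arrays treated with BA. The deposited table holds, per the labels, 1 normalized signal intensity per probe set and array on a linear scale. The software, the summary method and the scaling target are not given in the sources used here, nor is the dose of BA. The values show a scaling, since the 2% trimmed mean is the same in all arrays to within 6.4e-05 on the log2 scale, while the log2 medians range over 0.373. Scaling to a common trimmed mean assumes that most signal is unchanged between arrays. All 13 sample columns were used and 0 were left unused. The expression calls were not used here.

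Groups came from the sample titles. The title and description of Col-0 120 min array 1 give 120 min of BA, while its source field names the control solution, and the array was placed by its title. Groups were Col-0 with solvent, with 15 min and with 120 min of BA, and CKX1 with solvent and with 15 min of BA. The replicate numbers of the CKX1 titles pair the arrays, as far as the data show. Deviations from the group means correlated at 0.58, 0.63 and 0.73 in the 3 pairs of the same number, across probe sets, against a median of −0.35 between different numbers. The latter ranged from −0.51 to 0.47, the highest being solvent array 1 with 15 min array 4. Deviations cancel within a group, which pushes values between different numbers down.

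Of 22810 probe sets, 64 controls were left out, and probe sets whose mean log2 value lay under the 30th percentile were filtered, which left 15922 for testing. Values were taken as deposited, values under 1 were set to 1, and a pseudocount of 3.39, 0.1 of the table's median of 33.9, was added before log2. Fold changes are therefore on the log2(value + pseudocount) scale and understate the change of dim probe sets. The linear model of limma 3.58.1 in R 4.3.3 was fitted to all 13 arrays in 5 groups without a block, with 8 residual degrees of freedom and an intensity trend in the moderated variance. Benjamini-Hochberg adjustment was made per comparison, and an adjusted p under 0.05 was the threshold. Means ± SD are of deposited signals.

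The probe annotation listed 13513 of 22746 probe sets with 1 gene, 503 with several and left 8730 unlisted. Of those with 1 gene, 13436 matched the RefSeq gene table. A probe set that is not listed is unnamed here, which does not mean that it has no gene, and none was named from a probe set with several genes. Among those tested, 8748 had 1 gene, 311 several and 6863 were not listed.

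The genes to name were set by a rule. Per comparison it takes the 10 largest rises and the 10 largest falls among probe sets past the threshold that match 1 gene and whose groups do not overlap, every type-A response regulator and cytokinin oxidase, and up to 4 members past the threshold from each other list. No cytokinin oxidase was measured by a named probe set. Genes outside the rule are given as chosen after their values were seen. The 28 gene lists held 344 loci, of which 40 had a probe set with 1 gene and 33 were measured, so that 2 lists reached the 4 members needed for a set test and lists without a measured member have no result. Camera used a preset correlation of 0.01, with an estimated correlation and fry as alternatives. The groups, the model, the rule, the lists and all but 5 of the alternative model settings were chosen before the data were examined. Those 5, 2 further lists and the sets by gene symbol and organelle were chosen after seeing the data.

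The model was tested on simulated data with 200 changed probe sets per comparison among 15922. For a log2 change of 2 it recovered 35.8% in Col-0 at 15 min, 50.7% at 120 min, 46.3% between the times, 76.1% in CKX1, 50.7% between genotypes and 16.4% for the interaction. For a change of 1 it recovered at most 11.9%, in CKX1, and for a change of 4 at least 83.3%, in the interaction. Simulated noise was independent between probe sets and had the model's own spread, equal in all arrays. The estimated weights of the real arrays ranged from 0.22 to 4.52, so the shares recovered may not hold for these data. Alternatives were median-centring, quantile normalization, other pseudocounts and filters, fits of the compared groups alone, a replicate block, array weights, other variance models, a fold threshold and leaving out each array.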

Results

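Transcript levels were measured on Affymetrix Arabidopsis arrays in seedlings treated with the cytokinin 6-benzyl adenine (BA) or with its solvent. The plants were wild-type Col-0 or a line carrying 35S::CKX1, which overexpresses a cytokinin oxidase, an enzyme that degrades cytokinins. The 13 arrays comprised 2 of Col-0 with solvent, 2 of Col-0 after 15 min of BA, 2 of Col-0 after 120 min of BA, 3 of CKX1 with solvent and 4 of CKX1 after 15 min of BA. Solvent was applied for 2 h, which matches the 120 min treatment and not the 15 min treatment. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. The number of arrays, 2 to 4 in a group, limits the precision of every value.

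Signals of a typical probe set were alike in all arrays, with array medians from 30.5 to 39.5 units. Arrays of the same group correlated at 0.778 to 0.972 (median 0.881, 12 pairs) and arrays of different groups at 0.806 to 0.971 (median 0.884, 66 pairs), across probe sets, which are not independent replicates. The first principal component held 34.3% of the variance. Both Col-0 120 min arrays, Col-0 15 min array 2, CKX1 solvent array 3 and CKX1 15 min array 3 lay above 0 on it, at 34.7 to 77.0, and the other 8 arrays lay at −25.1 or below. The same 5 arrays had the highest signals of the 25S ribosomal RNA control, 92.5 to 803.7 units against at most 46.2 units in the others. They also had the highest maximum signals, controls included, at 6586.7 to 24629.9 units against at most 6558.4. The geometric mean of the spike controls was 3367.8 units in CKX1 15 min array 3 and at most 970.5 elsewhere. It did not divide the arrays in the same way, with 492.2 in CKX1 15 min array 2 and 419.0 in Col-0 120 min array 1.

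**Figure D1:**
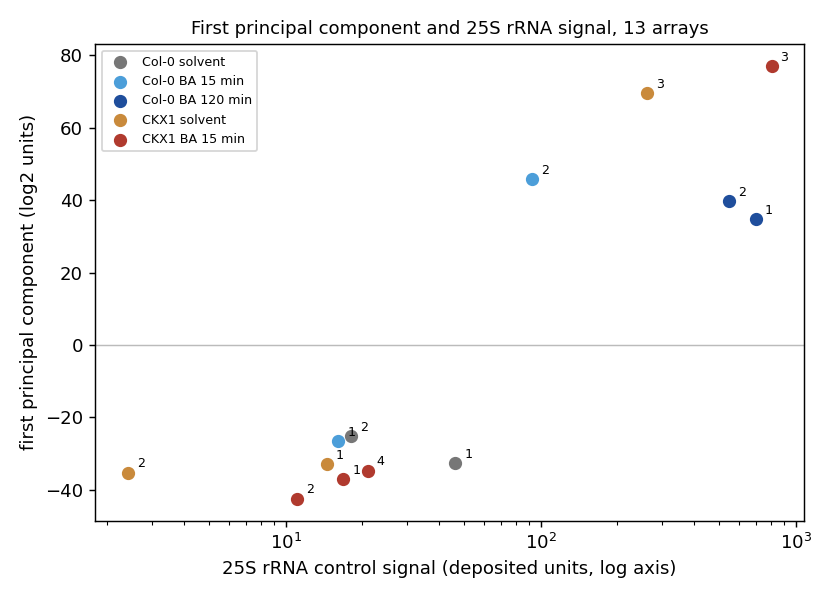
First principal component of the tested probe sets (vertical axis, log2 units) against the signal of the 25S ribosomal RNA control (horizontal axis, deposited units, log scale), 1 point per array, coloured by group and numbered by replicate. The 5 arrays above 0 have 25S signals of 92.5 to 803.7 units, and the other 8 arrays have at most 46.2 units.

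Among named genes, the lowest p-value in Col-0 after 15 min of BA was that of ARR15, a type-A response regulator of the class of early cytokinin response genes that dampen cytokinin signalling. Its signal was 7.0 ± 6.08 units (SD, n = 2) with solvent and 88.8 ± 43.8 units (n = 2) after 15 min, a log2 fold change of 3.2 (SE 0.60), and both BA arrays lay above both solvent arrays. This did not pass over all probe sets (limma, unadjusted p = 0.000202, adjusted p = 0.805), while 1 of the 2 measured type-A regulators passed when adjusted over the list alone. ARR16, the other one, had a log2 fold change of 1.23 (SE 0.64), and 0.70 to 1.76 over other settings. The list held 10 type-A regulators, of which only these 2 had a listed probe set with 1 gene, so the class as a whole was not assessed. Of the 2 measured cytokinin N-glucosyltransferases, UGT76C1 had 0.92 and UGT76C2 had 0.53, and 1 of the 2 passed when adjusted over the list alone.

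No probe set passed the threshold at 15 min in Col-0 (limma, 0 higher and 0 lower, lowest adjusted p = 0.805). At an unadjusted p under 0.05 there were 173 probe sets, against 796.1 if no probe set changed and the p-values were calibrated. A count so far below 796.1 makes that benchmark unreliable here, so few low p-values are no evidence that BA had no effect. Among the genes with the lowest p-values, chosen after their values were seen, AT1G21830 had a log2 fold change of 2.05 on one probe set and 1.38 on another, AT3G19850 had 1.55 and AT1G68670 had 1.22. AT3G50350 had −1.33 and UGT71C3, a glycosyltransferase, had −0.88. The unnamed probe sets 252374_at and 247406_at had 3.64 and 2.71, with lower p-values than ARR15.

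Expansins, which loosen cell walls, stood lower than other genes in Col-0 at 15 min under the preset correlation, with a median log2 fold change of −1.03 over the 4 measured members of the cell wall loosening list (camera adjusted p = 0.0131). The call was lost with adjusted p = 0.192 with an estimated correlation, and 0 members passed either over all probe sets or when adjusted over the list alone. Members were EXPB1 at −1.60, EXPB3 at −1.36, EXPA4 at −0.69 and EXPA8 at 0.00. Without Col-0 15 min array 2, which lies among the 5 arrays high in 25S signal, the median was −0.23 (adjusted p = 0.665). The 4 measured root markers had a median of −0.63 (adjusted p = 0.160), which became 0.019 without the same array.

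After 120 min of BA in Col-0, 3 named genes fell. GT72B1, a glycosyltransferase that conjugates phenolic compounds, went from 308.8 ± 97.7 to 25.2 ± 2.97 units (n = 2 each), a log2 fold change of −3.42 (SE 0.47). AT5G60520 went from 72.7 ± 4.03 to 5.45 ± 1.77 units, a change of −3.12 (SE 0.41), and LTI30, a dehydrin induced by cold and drought, went from 276.9 ± 46.5 to 52.9 ± 3.96 units, a change of −2.31 (SE 0.31). The unnamed probe sets 258487_at and 254197_at rose by 2.80 (SE 0.35) and 2.41 (SE 0.35), and 258586_s_at, which matches several genes, fell by 4.14 (SE 0.56). The signals of 258586_s_at after BA were 1.5 and 0.5 units, at or near the floor of 1. The size of its fall therefore rests on the floor and the pseudocount (−5.77 to −2.64 over other settings). In limma the 2 that rose and the 4 that fell had an adjusted p of 0.0332, except 254197_at with 0.0461. In each of them both BA arrays lay outside the range of the solvent arrays. Col-0 15 min array 2 lies with the 120 min arrays on the first principal component. In it GT72B1 had 79.9 units against 241.9 in array 1, and 258586_s_at 22.7 against 115.2. AT5G60520 was also lower and 254197_at higher than in array 1. LTI30 (325.9 against 317.1) and 258487_at (81.7 against 136) did not differ in the direction of their calls. An array difference may therefore contribute to the other calls, beside BA, which was not tested.

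Genes just short of the threshold at 120 min, chosen after their values were seen, included PRX27, a class III peroxidase, at −4.04, UGT76B1, a glycosyltransferase acting on small defence-related acids, at −3.11, AT2G41050 at −2.67 and AT3G12870 at −3.11. On the positive side were AT1G33055 at 3.81, AT5G10040 at 3.72 and AT1G21830 at 3.05. Their limma adjusted p-values were 0.0549 to 0.0704. Each of these genes passed over all probe sets in 8 to 10 of 20 or 21 other settings. AT2G41050 averaged 1.25 units after BA, near the floor of 1, and its value went from −4.18 to −1.42 over other settings.

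Cytokinin-linked genes of the fixed lists had positive values at 120 min, without passing over all probe sets. ARR15 had 2.96 (SE 0.60, limma adjusted p = 0.106), with 71.1 ± 13.2 units after BA, and ARR16 had 1.89 (SE 0.64, adjusted p = 0.280). Of the 2 measured type-A regulators, 0 passed over all probe sets and 2 passed when adjusted over the list alone. In 20 other settings ARR15 passed over all probe sets in 8 (lowest adjusted p = 0.000829) and ARR16 in 4 (lowest adjusted p = 0.00167). UGT76C2 had 1.38 and UGT76C1 had 1.32, and both passed when adjusted over the list alone. The same held for the auxin-conjugating enzymes WES1 (1.72) and GH3.3 (1.05) of the auxin response list. EIN3 (1.21), the ethylene-response transcription factor, and COR47 (−0.86), a dehydrin, were each the only measured member of their list. Adjustment over the list changes nothing for them. Their unadjusted limma p-values were 0.0350 and 0.0270, and adjusted over all probe sets 0.359 and 0.339. No adjustment was made across the lists.

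Other lists at 120 min held no member that passed over all probe sets. The root hair expansins EXPA7 (−1.95) and EXPA18 (−1.54) and the cortex marker CO2 (1.40) were the 3 of 4 root markers that passed when adjusted over the list alone, beside PYK10 at 0.16. The list's median was −0.69 (camera adjusted p = 0.585), as was the adjusted p of cell wall loosening, whose median was −0.74 with EXPB1 at −2.23, EXPB3 at −1.83, EXPA4 at 0.87 and EXPA8 at 0.35. The gibberellin receptors GID1A, GID1B and GID1C had 1.22, −0.26 and 0.68, the chlorophyll-binding LHCB4.1 had 0.70 and PORB of chlorophyll synthesis had −0.35. The rapid stress genes STZ and WRKY53 had −2.42 and −2.22, and DFR and UF3GT of anthocyanin synthesis had −1.46 and −1.09. PDF1.2 (defence), GI (circadian clock) and ATHSP22.0 (heat shock) had 1.00, −0.13 and 0.82. The ribosomal protein genes RPL4A and RPL28A had 0.28 and −0.30, and the reference genes PEX4, SAND and TIP41 had 0.41, 0.14 and −0.26.

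The 25S control signal was 622.1 ± 104.4 units (n = 2) in the Col-0 120 min arrays and 32.2 ± 19.9 units (n = 2) in the Col-0 solvent arrays. In this comparison 2028 probe sets had an unadjusted p under 0.05, against 796.1 by chance. That benchmark is unreliable here, given the count of 173 in Col-0 at 15 min. The median of all probe sets was −0.11 as deposited, 0.09 with each array centred on its median and 0.01 after quantile normalization. Leaving out Col-0 solvent array 1, solvent array 2, 120 min array 1 or 120 min array 2 ended all 6 calls. The count rose to 3672 (1435 higher, 2237 lower) in a fit of the 2 groups alone, to 228 without both CKX1 arrays numbered 3, and fell to 3 without the filter on low signals.

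Between 15 and 120 min of BA in Col-0, AT5G10040 rose by 4.54 (SE 0.60, limma adjusted p = 0.0416), from 5.40 ± 6.08 to 175.3 ± 17.1 units (n = 2 each). The dehydrin LTI30 fell by 2.53 (SE 0.31, adjusted p = 0.0243), from 321.5 ± 6.22 to 52.9 ± 3.96 units. The unnamed 258487_at rose by 3.36 (SE 0.35, adjusted p = 0.00987), and no other probe set passed, while 851 had an unadjusted p under 0.05. The type-A regulators had ARR15 at −0.23 (SE 0.60) and ARR16 at 0.66 (SE 0.64), and 0 of the 2 passed when adjusted over the list alone.

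Genes short of the threshold between the times included the expansin EXPA16 at 3.28, AT1G33055 at 3.63, the peroxidase PRX56 at −2.39, AT1G51805 at −2.13 and AT3G26450 at −1.92, with limma adjusted p-values of 0.149 to 0.198. Of the fixed lists, GH3.3 (1.40) and EXPA4 (1.56) passed when adjusted over their list alone. COR47 (−0.89), the only measured member of its list, had an unadjusted limma p of 0.0230, which such an adjustment leaves unchanged. The cell wall loosening list had a median of −0.06 (camera adjusted p = 0.480), which was 0.083 with median-centred arrays and 0.0087 after quantile normalization, and root markers had −0.32 (adjusted p = 0.989). The count of 3 was 5 without Col-0 15 min array 1, 1 without 15 min array 2, and 0 without either 120 min array or in a fit of the 2 groups alone.

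In CKX1 seedlings, 15 min of BA raised the unnamed probe set 247406_at from 6.13 ± 4.65 (n = 3) to 198.6 ± 66.5 units (n = 4), a log2 fold change of 4.48 (SE 0.39, limma adjusted p = 0.00156), higher in all 4 BA arrays than in any solvent array. It was the only probe set to pass, and 218 had an unadjusted p under 0.05. ARR15 went from 5.97 ± 4.71 (n = 3) to 21.1 ± 10.9 units (n = 4). Its log2 fold change of 1.40 (SE 0.46, limma unadjusted p = 0.0105) did not pass over all probe sets, and it was the 1 of 2 type-A regulators that passed when adjusted over the list alone. ARR16 had 0.68 (SE 0.49).

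The unnamed 252374_at, which had the next lowest p in CKX1, had 3.44 (adjusted p = 0.0780). Named genes with low p-values there, chosen after their values were seen, were AT1G68360 (2.15), AT3G50300 (1.66), AT1G21830 (1.42), AZG1 (1.29), a transporter of purines such as adenine, and AT1G06980 (1.24), with AT1G31920 at −1.61. Root markers had a median of 0.017 (camera adjusted p = 0.720), and −0.020 with median-centred arrays, and cell wall loosening had −0.15 (adjusted p = 0.720). Because the replicate numbers paired the CKX1 arrays, the replicate block was fitted too, and it gave 1 probe set as a fixed term and 3 as a random term. The count was 2 without CKX1 solvent array 2, without CKX1 15 min array 2 or without CKX1 15 min array 3, and 0 without both CKX1 arrays numbered 3 and Col-0 15 min array 2 (247406_at at adjusted p = 0.0724).

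The genotypes differed most in the unnamed probe set 245108_at, which was 8.01 higher on the log2 scale in CKX1 than in Col-0 with solvent (SE 0.53, limma adjusted p = 8.23e-05). Over all treatments its signal was 1939 ± 666 units in the 7 CKX1 arrays and 5.73 ± 4.71 units in the 6 Col-0 arrays. The unnamed 266353_at was lower in CKX1 by a log2 change of −4.59 (SE 0.48, adjusted p = 0.00557), with 1.87 ± 3.06 units in CKX1 against 113.4 ± 56.0 units in Col-0. All CKX1 arrays lay on one side of all Col-0 arrays for both. No probe set used here was listed under the CKX1 gene, so the overexpressed transcript itself was not checked by name.

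No named gene passed between the genotypes, and 686 probe sets had an unadjusted p under 0.05. The cytokinin N-glucosyltransferase UGT76C2 had −1.88 (limma unadjusted p = 0.0045) and was the 1 of 2 members that passed when adjusted over the list alone, with UGT76C1 at 0.31. Among genes of low p, chosen after their values were seen, QQS, an orphan gene linked to starch content, had 3.53, the subtilisin-like protease ATSBT5.2 had 2.47 and the peroxidase PRX25 had 1.47, while AT4G11190 had −4.62. The unnamed 247406_at had −3.38 (adjusted p = 0.0603). ARR16 had −0.84, and ARR15 had −0.13 as deposited and 0.056 with median-centred arrays. Cell wall loosening had a median of −0.63 (camera adjusted p = 0.121) and root markers −0.30 (adjusted p = 0.952). The median of all probe sets was −0.11 as deposited and 0.07 with median-centred arrays. Without Col-0 solvent array 1 or array 2 the call of 266353_at ended (adjusted p = 0.0679 and 0.345), and without CKX1 solvent array 2 the count was 4.

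The difference between the genotypes in the response to 15 min of BA was tested as an interaction. ARR15 had −1.80 (SE 0.76, limma unadjusted p = 0.0359, adjusted p = 1.00), the negative sign meaning a smaller increase in CKX1, and ARR16 had −0.54 (SE 0.80). No probe set passed (limma, 0 higher and 0 lower), and 169 had an unadjusted p under 0.05. Genes of low p, chosen after their values were seen, were the plastid genes clpP (−2.33) and matK (−1.68), AT1G31920 (−1.92) and AT3G19850 (−1.81). Cell wall loosening had a median of 0.88 (camera adjusted p = 0.210) and root markers 0.64 (adjusted p = 0.358), and CO2 of the latter had −1.67. These medians were 0.10 and 0.21 without Col-0 15 min array 2, and 1.65 and 1.06 without Col-0 15 min array 1. In simulated data, with independent noise of equal spread in all arrays, 16.4% of probe sets with an interaction of 2 on the log2 scale were recovered.

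**Figure D2:**
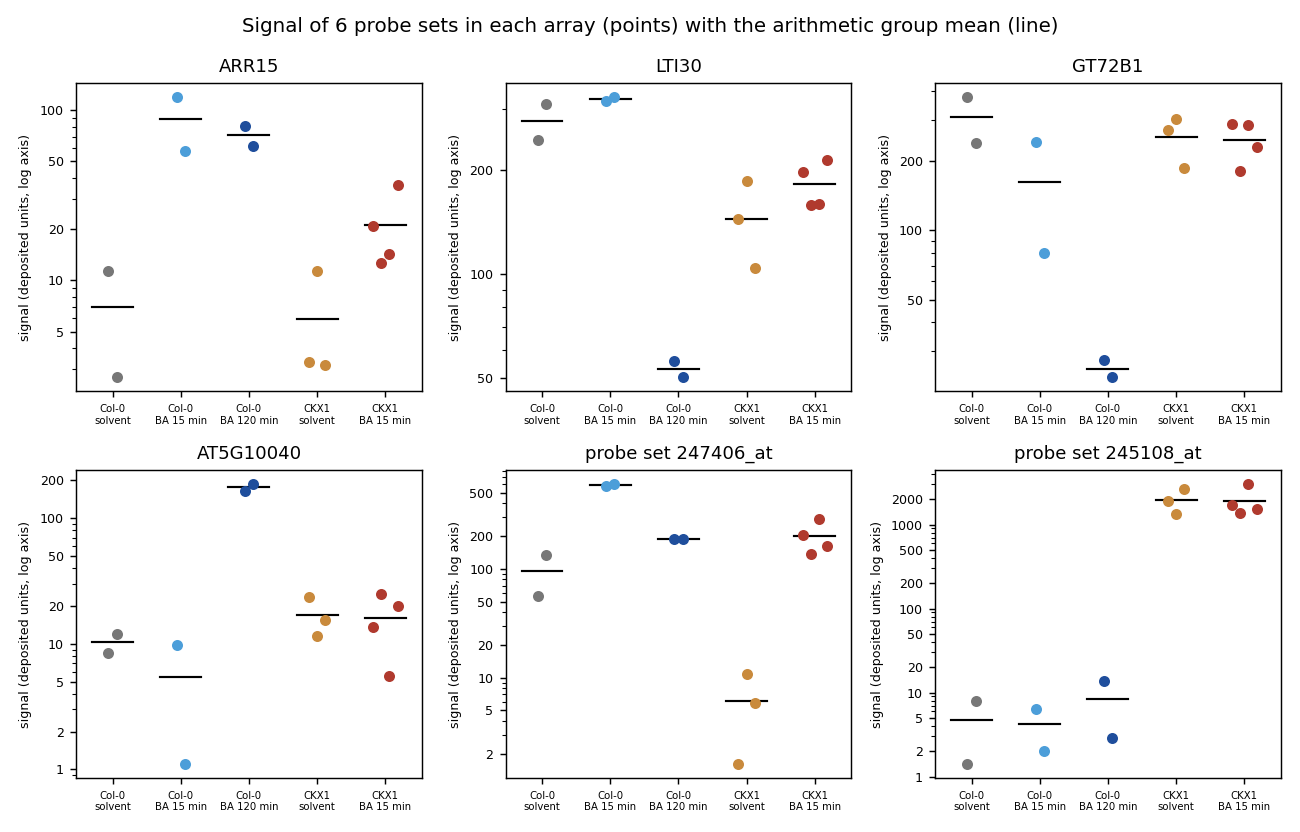
Signal (deposited units, log axis) of 6 probe sets in each of the 13 arrays, 1 point per array, with the arithmetic mean of each group as a line. ARR15 averages 88.8 units in Col-0 after 15 min of BA and 21.1 units in CKX1, LTI30 and GT72B1 are lowest at 120 min, AT5G10040 is highest at 120 min, 247406_at is higher in all 4 CKX1 BA arrays than in the CKX1 solvent arrays, and 245108_at lies at 1341.6 units or above in every CKX1 array.

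The fold changes of Col-0 at 15 min and at 120 min correlated across probe sets at r = 0.69 (Spearman's rho = 0.66), and 74.2% had the same sign. Genes are not independent replicates, and both comparisons share the 2 solvent arrays. In 20 simulations of unchanged groups that share them, r was 0.50 and 66.6% had the same sign. These simulations gave all arrays the same spread. The estimated array weights were 1.74 for the Col-0 solvent arrays and 0.59 for the Col-0 15 min arrays, so the simulations may overstate what sharing gives. The covariance was 0.247 against 0.150 simulated, a difference of 0.0974, and part of it may come from the shared controls, which are too few to split. The correlation rested on Col-0 15 min array 2, without which r was 0.10 although both solvent arrays were still shared. No calls were shared, and 0 were expected, since limma called 0 probe sets at 15 min (173 at an unadjusted p under 0.05).

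Col-0 and CKX1 at 15 min, which share no arrays, correlated at r = −0.13 (rho = −0.19) across probe sets, with 42.1% of the same sign and a covariance of −0.0186. The value went from −0.33 without CKX1 15 min array 3 to 0.25 without CKX1 solvent array 3. Of the 28 probe sets with the lowest p-values in either genotype or in the type-A list, chosen in part after their values were seen, 22 had the same direction in both and 6 had opposite directions. AT1G21830 had 2.05 in Col-0 and 1.42 in CKX1, while AT3G19850 had 1.55 and −0.26 and AT1G31920 had 0.31 and −1.61.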

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

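All tests of the causes weighed here were chosen after the results were seen. Of 39 sets of 4 CKX1 15 min values examined for a value far from the others, 3 held one, and chance gives about 1 in 20. They were the 25S control in CKX1 15 min array 3 (9.66 on the log2 scale), the first principal component in the same array (77.0), and AT1G68360 in CKX1 15 min array 2 (99.8 units, against 37.2 to 43.0 units in the other 3 arrays). The 25S control, outside the tested probe sets, averaged 622.1 units in Col-0 at 120 min, above the 32.2 units of the Col-0 solvent arrays.

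The response to 15 min of BA differed between the genotypes in 5 gene sets chosen after seeing the data, by camera with a preset correlation on the interaction. Plastid-encoded genes had a median of −1.14 (57 genes, adjusted p = 5.40e-12, and adjusted p = 0.742 with an estimated correlation). Mitochondrion-encoded genes had −0.69 (adjusted p = 0.0303, and adjusted p = 0.742 with an estimated correlation) and the PRX symbol family 0.58 (adjusted p = 0.0429, and adjusted p = 0.742 with an estimated correlation). The low-oxygen list had 0.54 (adjusted p = 0.0149) and the class III peroxidases, which share most members with the PRX family, 0.59 (adjusted p = 0.00387), both at adjusted p = 0.256 with an estimated correlation. The plastid median was −0.24 without Col-0 solvent array 2 and −1.97 without Col-0 solvent array 1. The other 4 sets lost most without Col-0 15 min array 2, which is among the 5 arrays high in 25S signal. Without it the low-oxygen list had −0.026, the class III peroxidases 0.093, the PRX family 0.055 and the mitochondrion-encoded genes −0.32, and none of these passed.

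The first pattern weighed is that 5 arrays stood apart on the first principal component. Treatment or genotype as the whole cause is argued against, since 3 groups had arrays on both sides. RNA degradation stays open because the controls disagree, with 2 of the 5 among the 5 arrays with the largest difference between 3' and 5' signals by the mean of the controls, 2 by actin, 2 by GAPDH and 4 by ubiquitin. Ribosomal RNA carried into the labelled material stays open too, since all 5 of them were the 5 arrays with the highest 25S signal, which 1 of 1287 ways to choose 5 arrays gives (share 0.000777). They were also the 5 with the highest maximum signal, so the 25S signal is not the only array property that goes with the component. The share takes the 25S signal as chosen beforehand, which it was not. Within the 5, CKX1 15 min array 3 was highest on both, but the order did not otherwise follow. Col-0 15 min array 2, with 92.5 units, lay at 45.8 on the component, above the Col-0 120 min arrays (34.7 and 39.7) with 695.9 and 548.2 units. A difference in the cultures was not tested, and both Col-0 120 min arrays lay on the same side, so for that group BA and the array difference may both contribute.

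The second pattern is that the Col-0 120 min fold changes resembled differences between replicates, with r across probe sets of 0.65 for Col-0 15 min array 2 minus its mate, 0.41 for CKX1 solvent array 3 and 0.27 for CKX1 15 min array 3. A BA response already present in Col-0 15 min array 2 is argued against as the whole cause by the 0.41 in an array without BA, which is also the highest of its group on a component of the 9 arrays outside the comparison (absolute values of 0.15 and 0.12 for the other ways to divide the 4 compared arrays into pairs). A first test of an array difference, the lowest of the 3 values (0.27), was replaced because those arrays had been picked on a component that includes the 120 min arrays, and a second, with the loadings of the 11 other arrays (r = 0.47), because these include the solvent arrays of the fold changes. In the third, that component of the 9 arrays had loadings that correlated with the 120 min fold changes at r = 0.42, against absolute values of 0.11 and 0.049 for the other ways. The other ways are few, cancel the group difference and leave only differences between close mates (r = 0.962 and 0.972). They are therefore a weak benchmark for the 0.41 and the 0.42, and cannot tell an array difference from BA. Part of those changes may be a difference between arrays, while a BA response in the same genes stays open, and genes are not independent replicates.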

How the results depend on the processing

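The settings with both CKX1 arrays numbered 3 left out, with Col-0 15 min array 2 left out too, with the 25S or the spike control signal as a covariate, with the random replicate block and both arrays numbered 3 left out, and the leave-one-out of the overlaps were chosen after seeing the data. Over 108 gene results, each a gene in a comparison, and their settings, 2147 values kept direction and side of the threshold, 213 gained and 55 lost it, and 13 turned direction. With 1 array left in a group it is assumed to vary like the other groups. The cause of a change was not tested. Fewer arrays or groups leave fewer degrees of freedom, which by itself does not raise a count. The fit shares 1 estimate of the spread over all groups. The Col-0 120 min count rose when both CKX1 arrays numbered 3 were left out, down-weighted or kept out of that estimate. Their weights were 0.33 (solvent) and 0.22 (15 min), against 2.53 for the Col-0 120 min arrays. The dimmest signals limit what can be seen, since fold changes there depend on the pseudocount.

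Col-0 at 120 min gave 6 probe sets, but 3 with no filter, 3672 with only the compared groups, 1027 and 831 with the replicate block as a fixed and as a random term, 3472 with array weights, 228 without both arrays numbered 3, 1604 without these and Col-0 15 min array 2, 147 with the 25S covariate, 1304 without both arrays numbered 3 and with the random replicate block, and 0 to 0 without each array. All 228 and all 831 were among the 3472, and 94 of the 147 were. The 3 of 120 against 15 min became 0 with only the compared groups, 52 and 51 with the fixed and random replicate block, 22 with weights, 13 without both arrays numbered 3, 752 without these and Col-0 15 min array 2, 264 and 6 with the 25S and spike covariates, 113 without both arrays numbered 3 and with the random block, and 0 to 5 without each array. Col-0 at 15 min gave 1 with weights, 1 without both arrays numbered 3 and with the random block, and 0 to 3 without each array. CKX1 at 15 min gave 3 with the random block, 2 with weights, 0 without both arrays numbered 3 and Col-0 15 min array 2, 2 with each covariate, 2 without both arrays numbered 3 and with the random block, and 1 to 2 without each array. The genotype count of 2 became 1 with the low pseudocount, 1 with the filter at the 50th percentile, 1 with only the compared groups, 4 with the fixed block, 9 with weights, 16 without both arrays numbered 3 and Col-0 15 min array 2, 6 with the 25S covariate, 1 without both arrays numbered 3 and with the random block, and 1 to 4 without each array. The interaction gave 0 under every setting run. In Col-0 same-numbered arrays deviated with r of −0.02 to 0.11, so the numbers do not pair the Col-0 arrays.

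Cell wall loosening in Col-0 at 15 min was −1.03 with an estimated correlation and with fry, both past the threshold no longer, −0.23 without both arrays numbered 3 and Col-0 15 min array 2, and −1.80 to −0.23 without each array. Fry asks whether a set moved at all, and camera whether it moved more than other genes, so the fry result answers a different question. At 120 min it was 0.59 with the 25S covariate. Between the times it was 0.083 median-centred, 0.0087 quantile-normalized, 1.25 with the 25S covariate and −0.50 to 0.53 without each array. In CKX1 it was 0.0060 with the 25S covariate and −0.51 to 0.17 without each array. With that covariate it passed in the genotype comparison (−0.66; −1.01 to −0.34 without each array) and the interaction (0.94). Root markers in Col-0 at 15 min were 0.019 without both arrays numbered 3 and Col-0 15 min array 2, and −1.04 to 0.019 without each array. In CKX1 they were −0.020 median-centred, −0.022 quantile-normalized, −0.073 with the fixed replicate block and −0.10 to 0.24 without each array. The overlap of Col-0 at 15 and 120 min was 0.10 without both arrays numbered 3 and Col-0 15 min array 2, 0.31 with the 25S covariate and 0.10 to 0.74 without each array. That of Col-0 and CKX1 at 15 min was 0.076 without those 3 arrays and −0.33 to 0.25 without each array.

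ARR15 between the times was 0.20 with the 25S covariate and −0.74 to 0.27 without each array. Between genotypes it was 0.056 median-centred, 0.18 quantile-normalized, 0.073 without both arrays numbered 3, with or without Col-0 15 min array 2, 0.011 with the spike covariate, 0.17 without both arrays numbered 3 and with the random block, and −0.76 to 0.51 without each array. ARR16 in the interaction was 0.011 without both arrays numbered 3, and 0.041 with the random block too.

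Of the gene sets chosen after seeing the data, the low-oxygen list turned direction in the interaction, at −0.026 without Col-0 15 min array 2 (1.23 without array 1). In Col-0 at 15 min it turned to 0.029 without array 2, alone or together with both arrays numbered 3, and was −1.23 without array 1.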

Other observations

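All gene sets and tests in this part were chosen after the data were seen, except the count over all splits of the CKX1 arrays. A list of genes known to respond to low oxygen, written after the lowest p-values had been seen, stood higher in Col-0 at 120 min of BA. Of 23 measured members 22 were positive, with a median log2 fold change of 1.43 (camera adjusted p = 4.85e-14, and adjusted p = 0.00992 with an estimated correlation), and 0 passed over all probe sets and 11 when adjusted over the list alone. All p-values and counts of this list include 6 members seen beforehand, with a median of 2.99, so they do not test an independent list. The 17 others had a median of 1.16 and were not tested as a set. Among the members seen beforehand, AT1G33055 had 3.81, AT5G10040 had 3.72 and AT1G19530 had 3.12. Among the others, HRA1, a transcription factor that attenuates the low-oxygen response, had 2.35, while PDC2, a pyruvate decarboxylase of fermentation, had 0.86 and AT5G27760 had −0.80. Against 15 min of BA the list's median was 1.92 (camera adjusted p = 4.92e-30, and adjusted p = 0.000841 with an estimated correlation). Over all probe sets 1 member passed, AT5G10040, which had been seen beforehand, and 19 passed when adjusted over the list alone. Col-0 at 15 min had −0.34, with 19 of 23 negative (adjusted p = 0.00101, and adjusted p = 0.137 with an estimated correlation). This rested on Col-0 15 min array 2, at −1.23 against 0.029 in array 1, and without array 2 the median against 15 min was 1.59 in place of 1.92. In CKX1 at 15 min it was −0.017 (adjusted p = 0.835). The list also stood higher in CKX1 than in Col-0 with solvent, with a median of 0.42 and 19 of 23 positive (adjusted p = 0.000183, and adjusted p = 0.169 with an estimated correlation). Of the 7 CKX1 arrays, 6 lay above the Col-0 solvent mean, at 0.090 to 0.93, and 0 members passed between the genotypes over all probe sets and 1 when adjusted over the list alone. The Col-0 120 min arrays were also those with 25S signals of 548.2 and 695.9 units.

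Class III peroxidases, enzymes of the cell wall and apoplast, had a median of −0.77 in Col-0 at 120 min, with 26 of 35 measured members negative (camera adjusted p = 1.98e-05). The call was lost with adjusted p = 0.0591 with an estimated correlation, and 0 members passed over all probe sets and 4 when adjusted over the list alone. These 4 were PRX27 at −4.04, PRX55 at −2.51, PRX11 at −2.50 and PRX56 at −2.34, beside the root hair expansins EXPA7 at −1.95 and EXPA18 at −1.54. Col-0 15 min array 2, which stands apart with the 120 min arrays, was at −0.86 for the peroxidases against −0.077 in array 1, while CKX1 solvent array 3 was at 0.42 and CKX1 15 min array 3 at 0.11. Across other settings the median went from −0.46 with no filter to −1.38 with the 25S covariate.

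Mitochondrion-encoded genes had a median of 1.05 in Col-0 at 120 min, with 11 of 11 positive (adjusted p = 2.85e-05), which was lost with adjusted p = 0.613 with an estimated correlation. Across other settings it went from 0.62 with the larger pseudocount to 1.39 after quantile normalization. Other arrays high in 25S signal also stood high for these genes, relative to the Col-0 solvent mean. CKX1 solvent array 3, without BA, was at 1.09 against 0.57 and 0.63 in its mates, Col-0 15 min array 2 at 0.67 against 0.11, and CKX1 15 min array 3 at 1.05 against 0.28 to 0.96. Plastid-encoded genes had 0.70, with 46 of 57 positive (adjusted p = 7.87e-05, and adjusted p = 0.813 with an estimated correlation). The Col-0 solvent arrays lay at 0.71 and −0.71, and the plastid median was 1.35 without solvent array 1, 0.0017 without solvent array 2 and 0.099 with the 25S covariate.

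The third pattern weighed is the higher level of the low-oxygen genes in Col-0 at 120 min. The array difference of the first principal component is argued against, since in the 3 other arrays high on it the list lay below its group mates, the highest difference being −0.32. The choice of members from values already seen is argued against as the whole cause, since the 17 members not seen beforehand had a median of 1.16, with 16 positive, against 2.99 for the 6 seen. Oxygen supply or handling of the vessels cannot be told apart from BA, because 0 other groups were treated with BA for 120 min, although the solvent arrays were also treated for 2 h. A response of these genes to BA may therefore be held only as a hypothesis.

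Chance was weighed for the 1 probe set called in CKX1 at 15 min by splitting the 7 CKX1 arrays into 4 and 3 in all 35 ways. As many calls came from 8 of the 35 splits, the real one included, so chance is not excluded on this count. The highest other split gave 254 probe sets and the next 203, and both put the arrays numbered 3 on the same side, but 10 of the 15 splits that do so gave 0. Of the 8 splits that part all 3 numbered pairs, the real one with 1 was the only one with a call, the highest other giving 0. These others differ in which array of each pair joins the unpaired array. That subset was chosen after the data were seen, and in it the real split is at best 1 of 8. It is therefore too small to argue against chance. The called probe set, 247406_at, was higher with BA in each of the 3 pairs and kept its call in 23 of 24 other settings. It was picked in these same arrays, where every BA array lay above every solvent array, so neither is separate support. At 15 min in Col-0, on arrays that the CKX1 comparison does not use, it had 2.71 (limma adjusted p = 0.805).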
